A study of Marchantia polymorpha with 6 samples.

How the data were processed

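Poly(A) RNA from thalli of Marchantia polymorpha, a liverwort, was sequenced in 6 samples, 3 grown with arsenite and 3 without. RNA was extracted with a Qiagen plant RNA kit, per the labels' protocols. The deposited values are whole-number read counts per gene, 1 file per sample, with no header line. The file names name htseq-count on the Galaxy platform as the counting tool. The aligner, the tool versions, the genome build, the gene annotation, the strand setting and any trimming are not given in the sources used here. Without a stated strand setting, reads from a gene and from an overlapping gene on the other strand cannot be told apart, and counts of near-identical paralogs are uncertain because the handling of reads with several placements is not given. Each file listed the same 19472 gene IDs and held no summary line for unassigned reads, so the share of unassigned reads is not reported.

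Gene symbols came from a table of the MpTak2_v7.1 assembly, which pairs locus tags with symbols. A locus tag was matched to a file ID by its number, and 17671 of 18391 locus tags (96.1%) had a matching ID. Of 17616 neighbouring matched tags on 1 chromosome, 98.3% had file IDs in the same order. Since the build behind the files is not given, no coordinates are printed. The table served only for names, for which genes are neighbours and for whether the spans of neighbours overlap. A symbol was present for 2597 of the 13544 tested genes (19.2%). The remaining genes could enter no list, so every statement on a gene group covers only its members with a symbol.

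Groups came from the sample titles and treatment labels. Library totals ran from 26579324 to 47532310 reads. No pair of libraries in a group differed by as little as sampling noise, since the lowest chi-square per degree of freedom within a group was 41.2. Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with TMM factors, the default low-count filter by group, and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. CPM values (reads per 1000000 mapped to tested genes) were computed from the deposited counts and TMM-scaled library sizes. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Fold changes are arsenite over control. Principal components used log2 CPM with a prior count of 2 for the 500 most variable genes.

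The tests, the alternatives, the rule for naming genes and 26 gene lists were fixed before the data were examined. The planned lists were written for product descriptions, while the table gives symbols only. They were therefore rewritten as symbol patterns after the table of names had been read and before the values of any gene were compared between groups. For 7 planned lists no unambiguous symbol was found: glutathione synthesis and recycling, sulfate and cysteine metabolism, copper, photosystems, carbon fixation, cytosolic ribosomal proteins and the proteasome were not analysed here. Symbols that could belong to such lists or to the antioxidants but have other readings, MpGR, MpCAT and MpCTR with a number and MpGCS1, were left out by choice, and 0 of the 11 tested passed. The PTB symbols were placed among phosphate transporters. Among 19 lists left, 18 had the 5 tested members needed for a set test. Camera, from limma 3.58.1, compared each list with all other tested genes at a preset inter-gene correlation of 0.01, then at an estimated correlation, for which camera uses 4 degrees of freedom, and fry tested each list on its own. At the rewriting, 2 lists of markers for other cell types and 14 further families were also fixed, the families being adjusted among themselves. A planned list of genes encoded by organelles and of ribosomal RNA was not analysed here, because no ID could be assigned to it. Named genes were the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap, plus the 2 members of each list with the smallest adjusted p at a mean of at least 1 CPM, plus phytochelatin synthase. The rule also named the arsenite transporter ACR3, glutamate-cysteine ligase and arsenate reductase, which carry no symbol in the table and are not analysed here by name. Other genes are named where they fill out a list's count, and these, with the count of phenylalanine ammonia-lyases, were chosen after their values were seen.

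The procedure was tested on simulated data with the real means and library sizes of 13544 genes and 200 genes changed. It called 50.9% of 116 genes changed 2-fold and 84.5% of 84 genes changed 4-fold, all with the right sign, and 5.80% of its calls were false. With no gene changed it made 0 calls and called 0 lists. Simulated genes were drawn independently, so the counts of called lists there do not cover list members that vary together. For the same reason the gene calls and their 5.80% of false calls do not cover variation that many genes of a library share. In the simulation with changed genes, 1 further list was called besides the list changed as a whole. Whether it held any of the other changed genes was not checked. Setting genes without a read in a group to the bound that 3 reads over the group allow moved the median of none of 36 lists and families by as much as the second decimal. Only 4 tested genes had no read in a group, so the medians could hardly move. Alternatives covered other scaling factors, other low-count filters, thinning to the smallest library, the 10 most abundant genes left out of library sizes, a stricter threshold, DESeq2 1.42.0, limma's voom with sample weights, the replicate number as a block, and each library left out in turn. Labels do not say whether the 3 samples of a group came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.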

Results

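Gene expression was measured by RNA sequencing in thalli, the flat plant body of the liverwort Marchantia polymorpha. The plants were of the genotype labelled Cam1, a male wild-type accession, and grew at 21 °C on half-strength Gamborg medium. The medium of 3 samples contained 2.5 µM sodium arsenite, a trivalent form of arsenic, and that of 3 control samples had none. Totals were 31573867, 29540543 and 26579324 reads in arsenite replicates 1, 2 and 3, and 47532310, 26691102 and 31240189 reads in control replicates 1, 2 and 3. Between 46 and 158 reads per library fell on 47 genes with IDs of the female U chromosome, against 62663 to 113154 reads on 146 genes of the male V chromosome. The series title concerns the arsenite transporter ACR3 and a domain that senses arsenic, and the comparison asks which transcripts differ in thalli grown with arsenite.

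Growth on arsenite was accompanied by higher transcript levels of 5 glutathione S-transferases, among them MpGST19. MpTIP2, a tonoplast aquaporin, and MpPTB4, placed among phosphate transporters by its symbol, were also higher, but lost their calls in 4 and 5 of 15 alternatives. Of 101 cytochrome P450s 14 were lower and 2 higher, with MpCYP829F2 reduced 38.5-fold. Of 20 terpene synthases 8 were lower and 1, the most abundant, was higher, and of 11 phenylalanine ammonia-lyases 4 were lower and 0 higher. Phytochelatin synthase, MpPCS, the enzyme that makes metal-binding peptides from glutathione, had 26.1 ± 3.62 CPM in controls and 27.3 ± 4.53 CPM with arsenite (SD, n = 3 each). Its log2 fold change was 0.07 ± 0.16 (SE), with a 95% interval from -0.31 to 0.45 (adjusted p = 0.839, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, used for all genes).

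Of 13544 genes tested, 566 changed, 276 upward and 290 downward, and 359 of them changed more than 2-fold (152 upward, 207 downward). Groups did not overlap for 3822 of the 13544 tested genes (28.2%), which chance gives for 10% of genes. An unadjusted p under 0.05 in edgeR's test was reached by 2860 of the 13544. A symbol was present for 62 of the genes that rose and 101 of those that fell. The median log2 fold change over all tested genes was -0.004, and the biological coefficient of variation was 22.8%. The number of calls depended on single libraries and on the test: it was 39 without arsenite replicate 2, 103 without control replicate 1, 148 without control replicate 3, 176 without control replicate 2, 338 without arsenite replicate 1, 57 at a false discovery threshold of 0.01, 1095 with voom and 1526 with DESeq2, whose calls included all 566. Of 38 named genes that passed, 8 lost their call in none of 15 alternatives, 17 in 1 to 4 and 13 in 5 or more, namely MpH2A.X.1, MpABCC1, MpLEA-like19, MpNIP, MpH4e, MpLOX4, MpPPO37, MpABCG1, MpBHLH5, MpGH18.1, MpPOD13, MpPOD66 and MpPTB4. Camera called 9 of 18 gene lists at a preset correlation, 5 upward and 4 downward, and 1 with an estimated correlation. The 9 other splits of the 6 libraries into equal groups gave 3 to 10 lists at the preset. Each of these puts 2 libraries of 1 treatment with 1 of the other and so keeps part of the treatment difference. They do not show how many lists would be called without such a difference. Fry's test for change in either direction passed for 15 of 18 lists, 2 of them without a gene that passed. The first principal component, with 59.4% of the variance, separated the groups, and the second, with 22.4%, set arsenite replicate 3 apart from arsenite replicates 1 and 2.

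**Figure D1:**
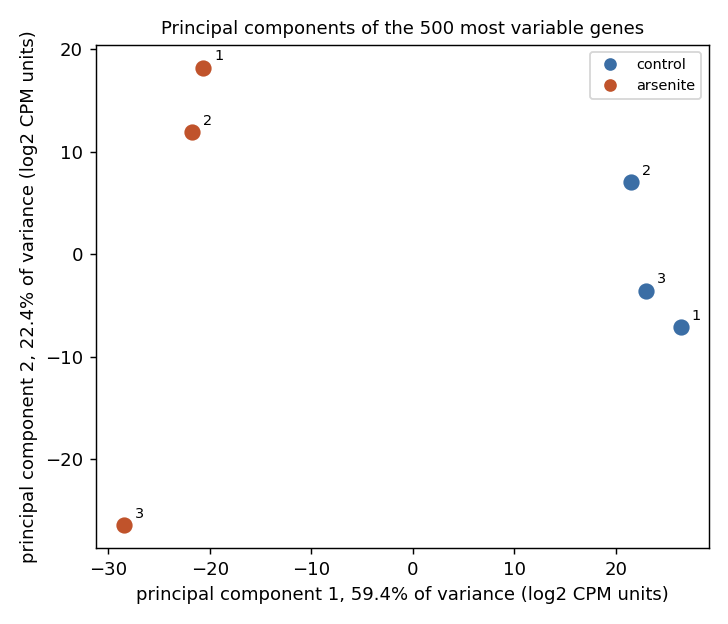
Principal components 1 and 2 of log2 CPM for the 500 most variable genes, in log2 CPM units, with each point a library labelled by its replicate number. Arsenite libraries lie between -28.5 and -20.6 on component 1 and control libraries between 21.5 and 26.4.

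Of 32 glutathione S-transferases, which attach glutathione to reactive compounds, 5 rose and 0 fell over all genes, or 8 and 2 adjusted over the list alone, while 27 did not pass. MpGST19 (Mp8g10560) rose from 174 ± 8.62 to 506 ± 43.5 CPM (SD, n = 3 each), a log2 fold change of 1.54 ± 0.11 (SE, adjusted p = 0.00407). MpGST38 (Mp2g03760) rose from 0.421 ± 0.0858 to 3.80 ± 0.772 CPM (log2 fold change 3.18 ± 0.31, adjusted p = 0.00639). MpGST12, MpGST30 and MpGST10 also rose, with log2 fold changes of 1.28, 0.97 and 0.86. Camera called the list upward (median log2 fold change 0.07, camera adjusted p = 0.00352), with adjusted p = 0.242 at an estimated correlation and 0.0804 with voom. Fold changes were positive for 18 members and negative for 14. List medians relative to the control mean were -0.02, 0.14 and 0.04 log2 units in arsenite replicates 1, 2 and 3. In control replicates 1, 2 and 3 they were 0.02, -0.02 and -0.04, so the groups overlapped. The glycosyltransferase MpUGT19 (Mp4g16860) rose from 10.4 ± 1.36 to 36.4 ± 5.74 CPM (log2 fold change 1.80 ± 0.16, adjusted p = 0.00553).

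Among transporters of phosphate and water, MpPTB4 (Mp4g16560) rose from 14.2 ± 4.29 to 37.1 ± 10.6 CPM (SD, n = 3 each; log2 fold change 1.39 ± 0.29, adjusted p = 0.0463). Its call ended in 5 of the 6 runs with a library left out. It was the 1 gene that passed among 13 tested genes of phosphate transport and starvation, but 7 rose and 0 fell adjusted over the list alone, and 12 of 13 had positive fold changes, with a median of 1.36. Members lay a median of 1.79, 1.16 and 0.95 log2 units above the control mean in arsenite replicates 1, 2 and 3, and -0.28, 0.47 and -0.17 in control replicates 1, 2 and 3. MpPTB4, MpPTB2, MpPTB5 and MpPTB7 were each highest in arsenite replicate 1 and, among controls, in replicate 2. MpPTB7 stood at 2.29 ± 0.733 CPM in controls and 5.84 ± 2.09 CPM with arsenite (log2 fold change 1.36 ± 0.34, adjusted p = 0.0791). This list had a camera adjusted p = 1.55e-05, and adjusted p = 0.242 with an estimated correlation. Of 7 aquaporins, 1 rose and 1 fell, or 3 and 1 adjusted over the list alone. MpTIP2 (Mp6g11780), of the class found in the vacuolar membrane, rose from 40.8 ± 7.0 to 105 ± 26.6 CPM (log2 fold change 1.37 ± 0.21, adjusted p = 0.0219). Its call ended in 4 of the 6 runs with a library left out. MpNIP (Mp8g11200) belongs to the class of aquaporins that in other plants conducts arsenite and other metalloids, and it fell from 34.3 ± 3.47 to 19.6 ± 2.77 CPM (log2 fold change -0.81 ± 0.14, adjusted p = 0.0322), a call that ended in 7 of 15 alternatives, among them all 6 with a library left out. The aquaporin list had a median of 0.53 and a camera adjusted p = 0.0485, which became adjusted p = 0.242 with an estimated correlation, 0.230 without arsenite replicate 1, 0.0713 without arsenite replicate 2, and 0.0556, 0.0545 and 0.148 without control replicates 1, 2 and 3.

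In the list of expansins, cellulose synthase-like D proteins, pectin methylesterases and related enzymes, 6 of 84 rose, 1 fell and 77 did not pass, or 17 and 4 adjusted over the list alone. MpCSLD7 (Mp5g24530) rose from 29.0 ± 1.15 to 54.9 ± 3.28 CPM (SD, n = 3 each; log2 fold change 0.92 ± 0.10, adjusted p = 0.00888), and MpCE8.5 (Mp2g19430), of the pectin methylesterase family, from 363 ± 70.3 to 802 ± 82.4 CPM (log2 fold change 1.14 ± 0.17, adjusted p = 0.0193). MpGH16.30, MpGH16.42, MpGH16.40 and MpCSLD1 rose by log2 fold changes of 1.48, 1.13, 0.61 and 0.62, while MpGH16.22 fell by 2.97 on the log2 scale. The list median was 0.44 (camera adjusted p = 1.67e-05, and adjusted p = 0.242 with an estimated correlation). Late embryogenesis abundant proteins and dehydrins, known from desiccation tolerance, had 2 of 46 members that rose and 0 that fell, or 13 and 1 adjusted over the list alone. MpLEA-like33 (Mp5g22700) had the largest rise among called genes with a symbol and a mean of at least 5 CPM, from 27.4 ± 9.01 to 116 ± 35.5 CPM (log2 fold change 2.08 ± 0.30, adjusted p = 0.0184). MpLEA-like19 went from 0.796 ± 0.538 to 6.80 ± 3.97 CPM (log2 fold change 3.04 ± 0.59, adjusted p = 0.0397). In this gene arsenite replicate 3 had 11.3 CPM and the 2 other arsenite libraries 5.14 and 3.93, and the call ended in 7 of 15 alternatives, among them all 6 with a library left out. The list median was 0.72 (camera adjusted p = 1.07e-05, and adjusted p = 0.424 with an estimated correlation). Its members lay a median of 0.29, 0.32 and 1.12 log2 units above the control mean in arsenite replicates 1, 2 and 3, and -0.12 to 0.16 in controls, and camera gave adjusted p = 0.00745 without arsenite replicate 3. Further large rises were those of MpGPAT6c, of the family that makes cutin precursors (log2 fold change 1.41), MpCuAO1, a copper amine oxidase (1.41), MpDIR20 (1.63) and MpPPO37 (1.54).

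Of 101 cytochrome P450s, oxygenases of specialised metabolism, 14 fell, 2 rose and 85 did not pass, or 21 and 4 adjusted over the list alone. MpCYP829F2 (Mp7g08070) fell from 24.0 ± 13.7 to 0.622 ± 0.0699 CPM (SD, n = 3 each; log2 fold change -5.27 ± 0.48, adjusted p = 0.00553). MpCYP829-like42 (Mp8g12170) fell from 13.7 ± 4.97 to 0.552 ± 0.229 CPM (log2 fold change -4.63 ± 0.42, adjusted p = 0.00553), and MpCYP829F1 (Mp3g14900) from 18.9 ± 6.21 to 2.45 ± 0.610 CPM (-2.95 ± 0.32, adjusted p = 0.00888). MpCYP716-like23 (Mp4g00450) fell from 16.9 ± 1.31 to 4.10 ± 0.384 CPM (-2.04 ± 0.15, adjusted p = 0.00407). The family CYP829 alone had 11 members that fell and 1, MpCYP829-like31, that rose among 36 tested. MpCYP716 was the other P450 that rose. Counts of such paralogs are uncertain where reads fit several copies, but CPM summed over the 36 CYP829 genes was also lower, at 828 ± 18.7 in controls and 570 ± 48.0 with arsenite, with a log2 ratio of -0.54 and no overlap between groups (an exact permutation test of 3 against 3 cannot go below a two-sided p of 0.1). The list had a median of -0.20 (camera adjusted p = 3.04e-06) and was the 1 list of 18 whose call held with an estimated correlation (adjusted p = 0.0354).

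Terpene synthases, which make volatile and oil-body terpenoids in liverworts, fell in 8 of 20 tested genes, rose in 1 and did not pass in 11, or 11 and 3 adjusted over the list alone. MpMTPSL9 (Mp1g25500) fell from 23 ± 10.1 to 2.40 ± 0.690 CPM (SD, n = 3 each; log2 fold change -3.26 ± 0.39, adjusted p = 0.0112). MpFTPSL3 (Mp6g04400) fell from 31.7 ± 8.50 to 3.39 ± 0.948 CPM (log2 fold change -3.23 ± 0.30, adjusted p = 0.00553). MpFTPSL2, MpFTPSL8, MpMTPSL18 and MpMTPSL19 fell as well, with log2 fold changes of -2.02, -2.43, -1.91 and -1.67. MpMTPSL-like, the most abundant of these genes, rose from 90.6 ± 17.2 to 205 ± 24.2 CPM (log2 fold change 1.18 ± 0.16, adjusted p = 0.0158). CPM summed over the 20 genes was 331 ± 36.3 in controls and 362 ± 22.2 with arsenite. The list median was -1.21 (camera adjusted p = 1.90e-07, and adjusted p = 0.10 with an estimated correlation).

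Phenylpropanoid and flavonoid synthesis had 15 genes that fell and 4 that rose among 151 tested, or 32 and 13 adjusted over the list alone, with 132 that did not pass. Phenylalanine ammonia-lyases, which divert phenylalanine into this pathway, were among those that fell: MpPAL8 went from 1434 ± 113 to 582 ± 124 CPM (SD, n = 3 each; log2 fold change -1.30 ± 0.18, adjusted p = 0.0153), and MpPAL7, MpPAL4 and MpPAL-like2 had log2 fold changes of -1.47, -0.96 and -1.48. The chalcone synthase-like gene MpPKS/CHS13 (Mp4g14180) fell from 48.2 ± 9.46 to 17.6 ± 1.09 CPM (log2 fold change -1.45 ± 0.16, adjusted p = 0.00888), and MpPKS/CHS15 and MpPKS/CHS11 by log2 fold changes of -0.99 and -1.07. Dirigent proteins, which steer the coupling of phenolic radicals, went both ways: MpDIR37 (Mp5g16880) fell from 132 ± 13 to 56.8 ± 3.94 CPM (log2 fold change -1.22 ± 0.11, adjusted p = 0.00553) and MpDIR49 fell by 2.79 on the log2 scale, whereas MpDIR20 rose. The cinnamate hydroxylase MpC4H2 rose by a log2 fold change of 0.61. The list median was -0.19 (camera adjusted p = 0.0117, with adjusted p = 0.242 at an estimated correlation and 0.0889 with voom).

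**Figure D2:**
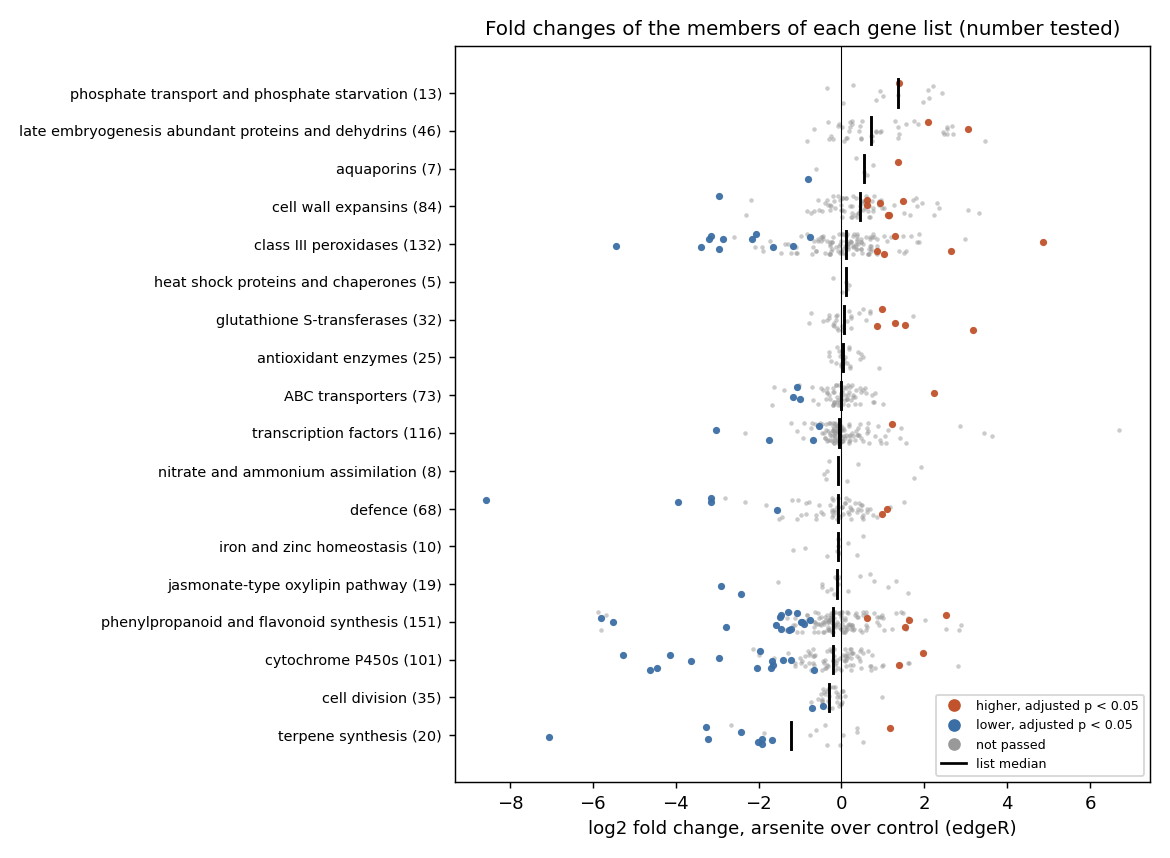
Log2 fold changes of the tested members of 18 gene lists, with each point a gene, coloured by whether it passed at an adjusted p under 0.05, and black bars at list medians. Medians run from -1.21 for terpene synthesis to 1.36 for phosphate transport.

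Class III peroxidases, secreted enzymes that use hydrogen peroxide, changed in both directions. Of 132 tested, 11 fell and 5 rose, or 16 and 13 adjusted over the list alone. MpPOD13 (Mp2g19200) fell from 34.5 ± 13.6 to 3.75 ± 3.15 CPM (SD, n = 3 each; log2 fold change -3.20 ± 0.62, adjusted p = 0.0397), MpPOD168 (Mp8g09900) from 505 ± 64.5 to 225 ± 28.3 CPM (-1.17 ± 0.14, adjusted p = 0.0123), and MpPOD66 and MpPOD143 by log2 fold changes of -2.85 and -2.15. With arsenite MpPOD13 had 7.31 CPM in replicate 1 and 1.32 and 2.61 CPM in replicates 2 and 3. The calls of MpPOD13 and MpPOD66 each ended in 5 of the 6 runs with a library left out, and over all alternatives their log2 fold changes ran from -4.12 to -2.79 and from -3.63 to -2.47. MpPOD69, MpPOD144 and MpPOD132 rose by 2.65, 1.29 and 0.85 on the log2 scale. The list's median of 0.11 and its mean of -0.05 differed in sign, and camera gave adjusted p = 0.949. The list was called upward without arsenite replicate 3 (adjusted p = 0.0493) and downward without arsenite replicate 1 (adjusted p = 0.0253).

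Among 25 other antioxidant enzymes, 0 passed with edgeR, also when adjusted over the list alone. At an unadjusted p under 0.05, 4 were higher, a smaller share than the 2860 of 13544 over all tested genes. DESeq2 called 1 of the 25 higher, and voom 1. MpMDHAR3, of ascorbate recycling, stood at 36.3 ± 8.71 CPM in controls and 67.6 ± 18.7 CPM with arsenite (SD, n = 3 each; log2 fold change 0.90 ± 0.25, adjusted p = 0.0970), and the ascorbate peroxidase MpAPX4 had a log2 fold change of 0.52 ± 0.16 (adjusted p = 0.13). None of 5 HSP90 chaperones passed with edgeR, DESeq2 or voom, and 0 had an unadjusted p under 0.05. MpHSP90-4 had 116 ± 3.56 and 126 ± 4.79 CPM (log2 fold change 0.11 ± 0.09, adjusted p = 0.492), and MpHSP90-2 a log2 fold change of 0.14 ± 0.13. Camera gave adjusted p = 0.308 for the antioxidant list and 0.730 for the chaperones, and fry's test in either direction 0.000747 and 0.594.

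Among the other metal and nutrient transporters, 0 of 10 genes of iron and zinc homeostasis passed with edgeR over all genes, or 1 higher and 3 lower adjusted over the list alone. At an unadjusted p under 0.05, 1 was higher and 3 were lower, DESeq2 called 2 lower, and voom called 1 higher and 2 lower. The zinc transporter-like MpZIP5 had 255 ± 54.1 CPM in controls and 139 ± 26.3 CPM with arsenite (SD, n = 3 each; log2 fold change -0.88 ± 0.20, adjusted p = 0.0587). The ferric reductase-like MpFRO1 had 106 ± 27.7 and 47.6 ± 16.6 CPM (log2 fold change -1.16 ± 0.29, adjusted p = 0.0740). MpZIP5 passed in 4 of 15 alternatives, among them edgeR with library totals as the only scaling and edgeR without the low-count filter. MpFRO1 passed in 2 of 15. The list was not called (camera adjusted p = 0.399). Of 73 ABC transporters, 3 fell and 1 rose, with equal counts adjusted over the list alone (camera adjusted p = 0.50). MpABCC1 (Mp1g25480), of the subfamily that in other plants moves glutathione conjugates into the vacuole, fell from 7.27 ± 1.04 to 3.45 ± 0.284 CPM (log2 fold change -1.07 ± 0.19, adjusted p = 0.0330), and likewise lost its call in 7 of 15 alternatives, among them all 6 with a library left out. MpABCG1 fell by 1.18 and MpABCB10 by 1.00 on the log2 scale, and MpABCG5 rose by 2.23, from 0.349 to 1.64 CPM. Of 8 ammonium transporters, 0 passed with edgeR or DESeq2, 1 was higher at an unadjusted p under 0.05, and voom called 1 higher. Their list had a median of -0.08 and a mean of 0.35 (camera adjusted p = 0.544), and MpAMT1.3 and MpAMT2.2 had log2 fold changes of 1.76 ± 0.84 and 0.41 ± 0.31 (adjusted p = 0.283 and 0.495).

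Lipoxygenases, which start oxylipin synthesis, had 2 members that fell: MpLOX15 from 3.77 ± 1.15 to 0.501 ± 0.265 CPM (SD, n = 3 each; log2 fold change -2.90 ± 0.46, adjusted p = 0.0253) and MpLOX4 from 95.7 ± 63.5 to 17.9 ± 4.99 CPM (-2.42 ± 0.47, adjusted p = 0.0395). The MpLOX4 call ended in 6 of 15 alternatives, 5 of them with a library left out. Control replicate 2 had 169 CPM of it against 54.2 and 64.2 in the other controls, and without that library the log2 fold change was -1.73 and the gene still passed. The jasmonate-type oxylipin list of 19 genes had 2 lower and 0 higher, or 5 and 5 adjusted over the list alone, and camera adjusted p = 0.741. The defence list had 5 of 68 genes lower and 2 higher, or 6 and 2 adjusted over the list alone (median -0.08, camera adjusted p = 0.50). In it the chitinase-family genes MpGH18.1 and MpGH19.2 went opposite ways, with log2 fold changes of -1.56 ± 0.29 and 0.98 ± 0.12 (adjusted p = 0.0342 and 0.0127). Cell division genes had 2 of 35 lower and 0 higher, or 5 and 0 adjusted over the list alone. Histones MpH4e and MpH2A.X.1 fell by 0.72 and 0.45 on the log2 scale (adjusted p = 0.0324 and 0.0488), though their calls ended in 6 and 10 of 15 alternatives, among them all 6 with a library left out. The list median was -0.29 (camera adjusted p = 0.0117, and adjusted p = 0.80 with an estimated correlation, 0.580 without arsenite replicate 1 and 0.357 without control replicate 3). Of 116 transcription factors, 4 fell and 1 rose, or 7 and 2 adjusted over the list alone. MpBHLH20, also called MpBNB, which specifies reproductive cell precursors, fell from 2.18 ± 1.04 to 0.261 ± 0.0606 CPM (log2 fold change -3.03 ± 0.45, adjusted p = 0.0193), and MpBHLH5 by 1.76, MpERF18 by 0.68 and MpR2R3-MYB9 by 0.54 on the log2 scale, while MpBHLH30 rose by 1.21. That list's median of -0.07 and mean of 0.11 differed in sign (camera adjusted p = 0.308), and the list was called downward without arsenite replicate 3 (adjusted p = 0.00745).

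**Figure D3:**
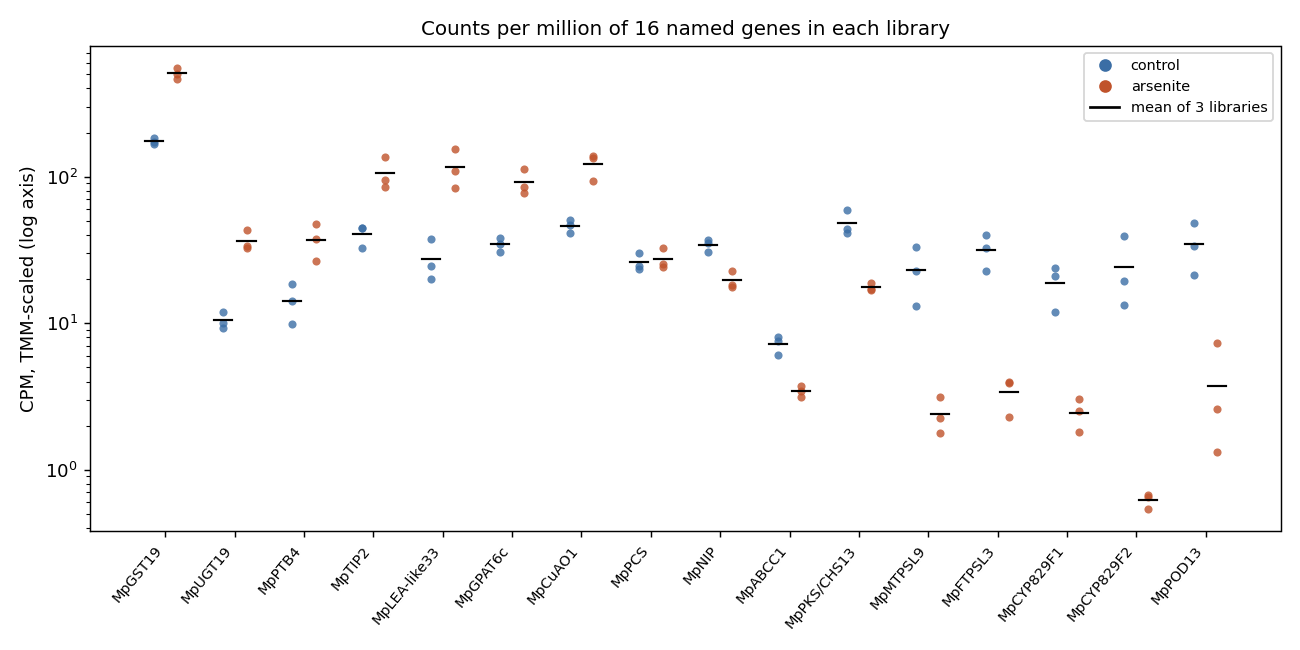
TMM-scaled CPM of 16 named genes on a log axis, with each point a library and black bars at the mean of 3 libraries per group. MpGST19 averages 174 CPM in controls and 506 CPM with arsenite, MpPCS 26.1 and 27.3 CPM, and MpCYP829F2 24.0 and 0.622 CPM.

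Of 4 tested genes of antheridia and sperm, male organs and cells that a thallus sample could hold, 0 passed with edgeR, DESeq2 or voom, and 1 was lower at an unadjusted p under 0.05. MpDUO1, a regulator of sperm formation, was at 1.08 to 1.65 CPM with arsenite and 1.68 to 3.22 CPM in controls (log2 fold change -0.90 ± 0.33, unadjusted p = 0.0284, adjusted p = 0.178; MpBHLH20, outside this list, fell), and the centrin gene MpCEN1 had a log2 fold change of 0.05 ± 0.10 (adjusted p = 0.820). Among 5 regulators of rhizoids, gemma cups and oil bodies, 0 passed with edgeR over all genes, 1 was higher adjusted over the list alone, at an unadjusted p under 0.05, with DESeq2 and with voom. The rhizoid regulator MpBHLH14, also called MpRSL1, had 13.5 ± 1.37 CPM in controls and 20.7 ± 1.82 CPM with arsenite (SD, n = 3 each; log2 fold change 0.62 ± 0.14, adjusted p = 0.0533), and the oil body regulator MpC1HDZ 56.1 ± 13.8 and 38.0 ± 10.3 CPM (-0.56 ± 0.25, adjusted p = 0.253).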

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

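With all 6 libraries, scaling, filtering, thinning and leaving out the 10 most abundant genes gave between 522 and 600 changed genes, against 566. None of the 566 changed sign under any alternative that gave it a value. All 566 had groups that did not overlap in CPM, so a change of sign could hardly occur. A threshold of 0.01 kept 57 genes (23 higher, 34 lower), 55 of them over 2-fold (22 and 33). DESeq2 called 1526 (819 and 707), 722 over 2-fold (361 and 361), and voom 1095 (562 and 533), 545 over 2-fold (255 higher). The cause of these differences between tests was not tested. With 1 library left out, which also means fewer samples, calls ran from 39 (without arsenite replicate 2) to 461 (without arsenite replicate 3): 16 to 233 higher, 23 to 228 lower, 39 to 330 over 2-fold, 16 to 155 of these higher and 23 to 175 lower, and 7 to 11 lists. Of 48 named genes, 38 passed, and 8 passed under every alternative run on them: MpUGT19, MpGST19, MpGST38, MpCYP829F2, MpCYP829-like42, MpCYP716-like23, MpFTPSL3 and MpDIR37. Without arsenite replicate 2, 30 of the 38 no longer passed. The replicate block gave 364 calls (145 higher, 39.8%), with 296 shared, and ended the call of 6 named genes and of no list. Deviations of same-numbered libraries correlated at 0.008, -0.11 and 0.19, and not every library correlated best with its own number. Arsenite replicate 1 correlated at 0.41 with control replicate 2 and at -0.45 with control replicate 3. The numbers thus gave no clear sign of pairing, though 3 libraries per group cannot exclude it. Of 9 called lists, 1 held with an estimated correlation, 5 with that correlation but the degrees of freedom of the preset run (chosen after seeing the data), 5 with fry and 6 with voom, which ended the calls of glutathione S-transferases (adjusted p = 0.0804), phenylpropanoid synthesis (0.0889) and aquaporins (0.141). The aquaporin call ended in 13 alternatives, among them 5 of the 6 with a library left out. The class III peroxidase list, not called with all libraries, turned upward without arsenite replicate 3 (adjusted p = 0.0493) and was called downward without arsenite replicate 1 (adjusted p = 0.0253), with 0.948 the highest when a library was left out and 0.989 over all alternatives, and the cause was not tested. Limiting the compared genes to those with a symbol, chosen after seeing the data, left 6 lists. Principal component 1 took 47.5% of the variance over all tested genes. The planned run without organelle-encoded genes was not run, since no ID could be assigned to an organelle. Thinning to the smallest library left 522 calls and ended those of MpH2A.X.1 and the aquaporin list (adjusted p = 0.0547). The transcription factor list was called downward without arsenite replicate 3 (adjusted p = 0.00745).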

Other observations

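The single genes named here, and the tests of sequencing depth, of summed terpene synthases, of oil body genes and of correlated list members, were chosen only after the result was seen. The auxin efflux carrier MpPIN4 fell from 168 ± 7.99 to 67.3 ± 12.2 CPM (SD, n = 3 each; log2 fold change -1.32 ± 0.14 SE, adjusted p = 0.00888), and the influx carrier MpAUX1 from 210 ± 12.6 to 133 ± 4.77 CPM (-0.66 ± 0.09, adjusted p = 0.0175). The plasma membrane proton pump genes MpHA2 and MpHA18 rose by 1.13 and 2.63 on the log2 scale, and MpACTIN7 by 0.72. MpHA18 averaged 0.825 CPM in controls and 5.03 CPM with arsenite. Fatty acid desaturases MpFAD6, MpFAD8 and MpFAD9 rose by log2 fold changes of 0.69, 0.54 and 0.98. The related acyltransferases MpGPAT6c and MpGPAT6d went opposite ways, by 1.41 and -0.94. Among genes without a symbol, Mp8g17780 rose from 34.3 ± 6.93 to 255 ± 37.9 CPM (log2 fold change 2.90 ± 0.19, adjusted p = 0.00318), and Mp7g05530 fell from 71.5 ± 4.30 to 4.74 ± 1.02 CPM (-3.92 ± 0.18, adjusted p = 0.000622, the smallest of all).

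Of 14 further families, 3 were called lower by camera and 0 held with an estimated correlation. Dirigent proteins and chalcone synthase-like genes also belong to the phenylpropanoid list, so their calls are not separate from that list's call. Among 39 dirigent proteins 4 fell and 1 rose, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.00706, and adjusted p = 0.183 with an estimated correlation). Among 24 chalcone synthase-like genes 3 fell and 0 rose, or 9 and 1 adjusted over the list alone (adjusted p = 0.000390, and adjusted p = 0.183 with an estimated correlation). Among 24 NPF nitrate and peptide transporters 2 fell and 0 rose, or 9 and 1 adjusted over the list alone (adjusted p = 0.00284, and adjusted p = 0.183 with an estimated correlation), with MpNPF5 and MpNPF24 at log2 fold changes of -2.24 and -1.88. Among families not called, UDP-glycosyltransferases had 3 lower and 2 higher of 32, with MpUGT36, MpUGT32 and MpUGT5 at -2.36, -2.57 and -2.27 and MpUGT19 and MpUGT22 at 1.80 and 0.68. Of 48 cupins 4 rose and 3 fell, with MpCupin75, MpCupin69, MpCupin66 and MpCupin19 at 4.05, 4.04, 3.33 and 1.19 and the neighbours MpCupin15 and MpCupin16 at -2.42 and -1.69. MpCupin75, MpCupin69 and MpCupin66 had few reads, at 0.133, 0.183 and 0.260 CPM in controls and 2.17, 3.01 and 2.65 CPM with arsenite. Class C dioxygenases had 4 of 29 lower and 1 higher, polyphenol oxidases 2 and 2 of 42, glycoside hydrolases 4 lower and 6 higher of 109, O-methyltransferases 1 of 13 higher, SAUR genes 1 of 14 higher, MATE transporters 1 and 1 of 13, and receptor-like kinases of the RLK-Pelle families 1 and 1 of 88. Of 21 autophagy genes 0 passed with edgeR, with 3 lower at an unadjusted p under 0.05, 1 lower with DESeq2 and 0 with voom. Of 72 pentatricopeptide repeat genes 0 passed with edgeR, DESeq2 or voom, with 1 higher and 2 lower at an unadjusted p under 0.05. Autophagy and pentatricopeptide repeat genes both had a smaller share there than all tested genes, with 2860 of 13544.

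Genes called in the same direction lay side by side more often than shuffled calls would place them. Among 13252 tested genes placed by the name table, 48 pairs of neighbours were called in the same direction, against a mean of 11.7 and a highest of 26 in 10000 shuffles (permutation p = 1e-04, the smallest they can give), and 6 pairs in opposite directions. A stretch of phenylpropanoid genes held MpPAL7 beside MpPKS/CHS11, MpPAL-like2 beside MpPKS/CHS13 and MpPKS/CHS15 beside MpPAL4, all lower. All 48 pairs had spans that do not overlap in the name table (shuffled mean 11.5). This argues against counting reads of a gene for an overlapping neighbour only if the annotation used for counting, which is not given, has such spans. The 5 pairs from different symbol families, where shuffles gave a mean of 0.379, argue against reads shared between the genes of a pair. They cannot exclude sharing among copies, because the pairs of the phenylpropanoid stretch are among them. Reads shared among its PAL copies and among its CHS copies could also give such pairs. For the 8 pairs within a family, sharing of reads stays open. Their fold changes differed by a median of 0.550 combined standard errors, between the bounds set in advance. The 35 pairs with a gene lacking a symbol were not tested. Shared regulation of neighbouring genes may be a candidate explanation, and no biological explanation was tested.

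Of 20 terpene synthases 8 fell and 1 rose, and of 36 CYP829 genes 11 fell and 1 rose. For CYP829 as a whole, movement of reads among its 36 tested genes is argued against, because their summed CPM was lower too. It was 828 ± 18.7 in controls and 570 ± 48.0 with arsenite (SD, n = 3 each). The log2 ratio was -0.54, and every arsenite library lay below every control. The sum cannot decide for single copies, nor for reads moved to copies outside the 36 or dropped because they fit several copies. For the terpene synthases the values are compatible with movement of reads between copies. Their sum was 331 ± 36.3 and 362 ± 22.2 CPM (log2 ratio 0.13), as MpMTPSL-like rose. Without that gene the sum was 240 ± 19.5 and 157 ± 2.00 CPM. Whether reads moved to MpMTPSL-like was not tested at the level of sequence. Unequal depth is argued against, because after thinning to the smallest library the larger adjusted p of the terpene and P450 lists was 3.21e-06, though with an estimated correlation the terpene list had adjusted p = 0.10. A hypothesis is a lower share of oil body cells, which store terpenoids: of 5 oil body genes listed from background knowledge after some of their values had been seen, MpSYP12B, MpABCG1, MpERF13, MpR2R3-MYB2 and MpC1HDZ had log2 fold changes of -1.41, -1.18, -1.08, -0.64 and -0.56, with 2 of 5 passing. Their median of -1.08 lay within their standard deviation of 0.363 from the terpene median of -1.21. Without MpMTPSL-like the terpene median was -1.67, farther from the oil body median than that standard deviation. The comparison thus hangs on 1 gene, and a lower share of these cells and lower expression within them cannot be told apart.

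The number of lists called at a preset correlation is open to members that vary together between libraries whatever the treatment. Estimating the correlation also lowers the degrees of freedom to 4, so each list was also tested at its estimated correlation with those of the preset run. For the cytochrome P450 list camera's adjusted p was 0.0354 with an estimated correlation of -0.005, below the preset of 0.01. Here too 4 degrees of freedom leave the correlation uncertain, so this explanation is argued against only as far as the estimate holds. Of the other 8 called lists, with adjusted p of 0.10 to 0.80 in that run, 4 lost their calls through the correlation alone, and for them the values are consistent with it: aquaporins and phosphate transport (both adjusted p = 0.0740), late embryogenesis abundant proteins (0.254) and cell division (0.764). For aquaporins the unadjusted p moved only from 0.0243 to 0.0283. The calls of terpene synthesis, cell wall enzymes, glutathione S-transferases and phenylpropanoid synthesis held at the correlation alone, with 0.0494 the highest adjusted p, and ended with 4 degrees of freedom. For these 4 lists it stays open, since 4 degrees of freedom leave the correlation uncertain. There are 10 splits of the 6 libraries into equal groups, too few for a share under 0.05. All but the grouping by treatment mix the treatments unequally, so they keep part of the treatment difference. The grouping by treatment gave 566 genes, 359 over 2-fold and 9 lists, and the highest of the other splits gave 0, 0 and 10. Only 1 of the 10 splits reached 566 genes, 1 reached 359 over 2-fold, and 2 reached 9 lists.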
